A study of Mus musculus with 44 samples.

How the data were processed

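RNA of liver, lung, spleen and whole blood of mice given a faecal suspension or saline was hybridized to Illumina mouse arrays, 1 array per sample and 44 arrays in all. Per the labels, tissue RNA was purified on RNeasy columns, blood RNA was collected in PAXgene tubes and cleared of globin RNA, quality was checked on a Bioanalyzer, and biotinylated cRNA was made with the MessageAmp kit. The labels name BeadStudio 3.23 as the processing software. The authors deposited a table of non-normalized signal intensities for 45281 probes. Beside each signal the authors deposited a detection p-value, low where a signal lies above background. The authors also deposited a matrix of log2 values whose array medians nearly agree within each tissue (6.967 to 7.583 over all arrays), and their normalization method is not given in the sources used here. Every array had its lowest signal well above 0, so no background had been subtracted. Array medians of the signal ran from 97.1 to 225.8, and the highest signals, 46977 to 70533, lie near the scanner's ceiling, so changes of the brightest probes may be compressed. Between 28.49% and 47.76% of the probes of an array had a detection p under 0.01, and the number of arrays limits the precision.

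Of the probes 34885 carried 1 gene symbol, 18 several and 10378 none. A mouse annotation matched 34818 of the first, with 10 symbols updated, giving 19053 genes. Arrays were grouped by tissue and by sham, 6 h or 24 h as the labels give them, and every array was used. In each tissue the signals were background-corrected and quantile normalized with limma's neqc, with an offset of 16. A probe was kept where its detection p was under 0.01 in at least 3 of the 11 arrays of the tissue, and the probe with the highest mean over the tissues stood for each gene. Limma 3.58.1 in R 4.3.3 fitted the 3 groups of a tissue with lmFit and eBayes, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The common response counts genes past that threshold in the same direction in every tissue. The tissue difference is limma's moderated F test of the interaction of tissue and treatment over the 8120 genes tested in all 4 tissues. For a gene above background in no array of a group, the fold is a lower bound computed against the background level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

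The 45 gene lists were written from general knowledge before the data were examined, as were the comparisons, the main test, the rule for named genes and the alternatives, apart from alternatives added after values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The named genes are, for each comparison with sham, the 6 highest and 6 lowest log2 fold changes among genes past the threshold whose PCI arrays lie on one side of all sham arrays. They include up to 4 members past the threshold with the largest change in each list, and always a panel of 15 acute phase and cytokine genes. Between the times they are the 5 highest and 5 lowest, for the common response the 10 genes in each direction with the largest smallest change over the tissues, and for the tissue difference the 10 with the widest range. Gene models without a proper name, and genes whose probes disagree in sign, were passed over.

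Arrays sit on 5 slides per tissue, numbered here 1 to 5 by the positions they hold, which exchanges slides 2 and 3 of spleen against their order. By these numbers slide 5 holds all 3 groups and slides 1 and 3 hold 6 h and 24 h arrays, so values against sham are also given with the slide as a block and within slide 5. By these numbers the same place holds the same group in all 4 tissues, while replicate numbers follow the place only in part. Alternatives were no background correction, another normexp with an offset of 50, cyclic loess, 1 normalization of all 44 arrays, the authors' log2 matrix, no filter, a stricter filter, all probes, slide or replicate blocks, a fit of 2 groups alone, trend and robust eBayes, array weights, an absolute log2 fold change of at least 1, and leaving out each array.

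The procedure was tested on simulated data, drawn from each gene's mean and spread within groups, with known changes added to 50 genes per size. In the comparisons at 6 h it recovered 26%, 46%, 56% and 14% of log2 changes of 1 in liver, lung, spleen and blood, 76%, 82%, 90% and 76% of changes of 2, and at least 92% of changes of 3. Between 2 and 14 unchanged genes were called per comparison. The common response recovered 91.5% of 200 changed genes with 0 false calls. The tissue difference recovered 98% of 200 genes changed by 4 in lung alone. It also called 39 unchanged genes, more than its nominal share of 5%. The part of correlations that shared sham arrays produce was estimated from 50 simulations.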

Results

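Total RNA of liver, lung, spleen and whole blood from 8-week-old female C57/BL6 mice was measured on Illumina bead arrays. The mice had received human faeces in suspension by injection into the peritoneum, a model of abdominal sepsis called PCI in the labels, or saline (sham). PCI mice were sampled after 6 h or 24 h, and the labels give no sampling time for the sham mice. Each of the 4 tissues has 3 sham arrays and 4 at each time, 44 arrays in all, and their number limits the precision. Nothing says that the replicates of a group came from separate animals, so a p-value measures the spread between these samples, which may be technical. An array detected between 28.49% and 47.76% of the probes. The series follows the response that several tissues share in murine sepsis. The comparisons ask which genes differ from sham at each time in each tissue, which differ between the times, which move the same way in every tissue, and which respond differently from tissue to tissue.

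Values are log2 fold changes ± standard error from limma, over 4 PCI and 3 sham arrays, and each adjusted p is limma's. A gene said to have risen or fallen passed an adjusted p of 0.05, and all 4 PCI arrays lay on one side of all 3 sham arrays unless the text says otherwise. Counts of list members go by the threshold alone. In every tissue 1 sham array carried raised acute phase transcripts. Saa3, an acute phase protein, stood at a log2 intensity of 15.78 in liver sham replicate 3 against 7.84 and 7.89 in the other liver sham arrays. It stood at 13.89 in lung sham replicate 3 against 6.6 and 6.97, at 12.30 in spleen sham replicate 1 against 5.63 and 5.94, and at 14.83 in blood sham replicate 1 against 5.07 and 8.58. Conversely, liver 24 h replicate 3 had a Saa3 value of 7.40, against 15.86 to 15.92 in the other liver arrays at 24 h.

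**Figure D1:**
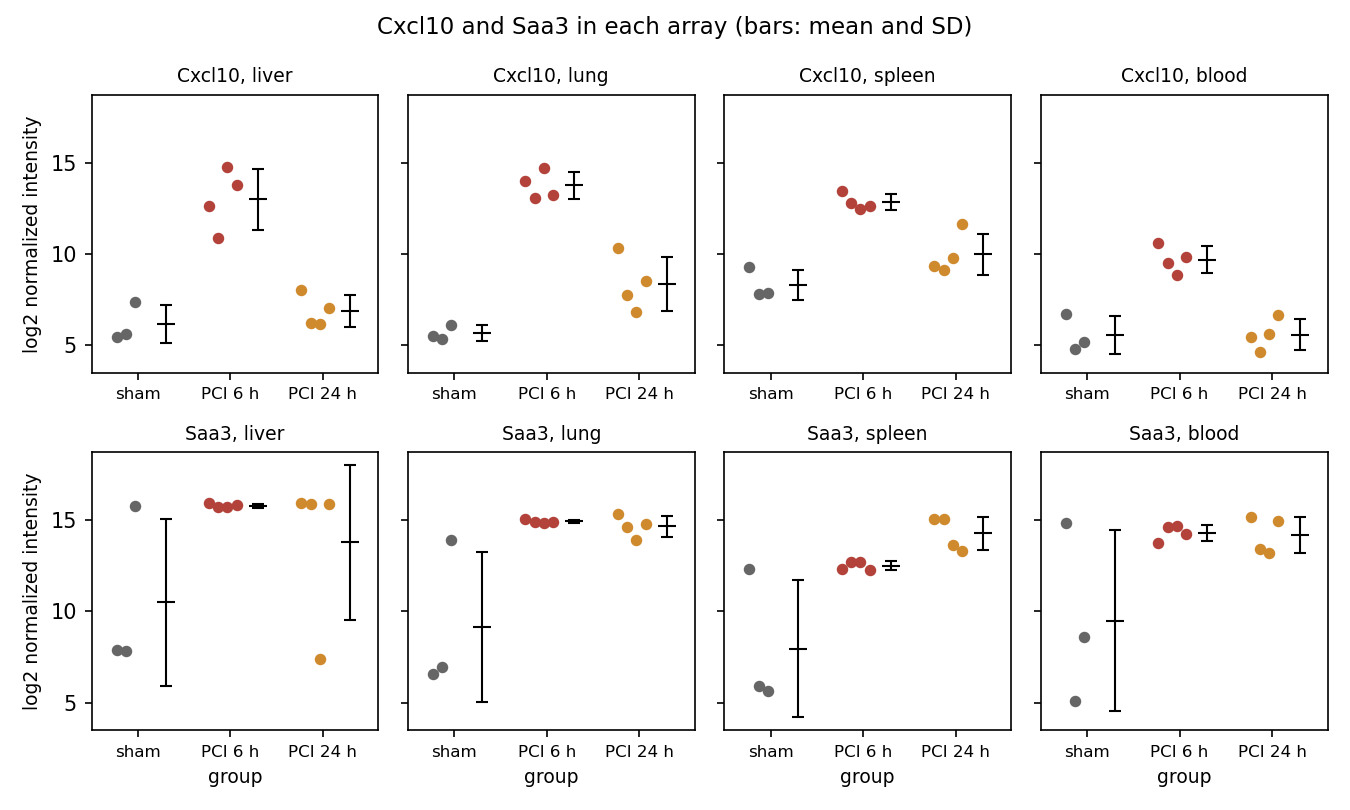
Log2 normalized intensity of Cxcl10 and Saa3 (y axis) in each array by group (x axis), with the mean and SD of each group. Cxcl10 at 6 h lies above every sham array in all 4 tissues, and 1 sham array per tissue has Saa3 far above the others of its group, for example 15.78 in liver.

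At 6 h the liver carried far more chemokine and interferon-induced transcripts than after sham treatment, and fewer of the bile acid enzyme Cyp7a1. Cxcl10, a chemokine that attracts activated T cells, rose 115-fold (log2 6.85 ± 0.82, adjusted p = 0.00131; 6.88 with the slide as a block and 7.29 within slide 5). Ifit2, an interferon-induced antiviral gene, rose 60.6-fold (log2 5.92 ± 0.46, adjusted p = 0.000148). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was above background in all 3 sham arrays and in none of the 4 PCI arrays, at least 74.8-fold lower (adjusted p = 0.0297). In sham it stood at 13.01 and 13.62, and at 8.49 in the raised array. G0s2, an inhibitor of lipolysis, fell by 4.17 ± 0.46 (adjusted p = 0.000816), and Dbp, an output gene of the circadian clock, fell by 4.10 ± 1.19 (adjusted p = 0.0445).

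Of 33 interferon-stimulated genes, 29 rose, 4 did not pass, and 32 rose when adjusted over the list alone. Their median was 2.69, or 2.65 with the slide as a block and 2.23 within slide 5 (camera adjusted p = 1.53e-29, adjusted p = 0.163 with an estimated correlation). Examples are the antiviral gene Rsad2 (5.50 ± 0.63), its genomic neighbour Cmpk2 (4.98 ± 0.43) and the guanylate-binding protein Gbp2 (4.53 ± 1.35). Among 29 genes of Toll-like receptor and NF-kappaB signalling, 19 rose and 1 fell (24 and 1 adjusted over the list alone), including the endotoxin co-receptor Cd14 (6.33 ± 1.70), Tlr2 (5.77 ± 1.10) and the NF-kappaB inhibitor Tnfaip3 (4.36 ± 1.29). Their median was 2.05, or 2.17 with the slide as a block and 2.14 within slide 5 (camera adjusted p = 2.49e-13, adjusted p = 0.213 with an estimated correlation). Negative feedback regulators of cytokine signalling had 13 of 23 higher and 1 lower (17 and 1 adjusted over the list alone). They include Cd274, the checkpoint ligand PD-L1 (4.32 ± 0.62), and Socs3, an inhibitor of cytokine receptor signalling (3.76 ± 0.92). Their median was 2.38, or 2.42 with the slide as a block and 2.61 within slide 5 (camera adjusted p = 3.25e-09, adjusted p = 0.213 with an estimated correlation). The anti-inflammatory cytokine Il10, above background in no sham array and in all 4 PCI arrays, was at least 8.78-fold higher (adjusted p = 0.00585). Neutrophil markers rose in 11 of 17 cases (13 adjusted over the list alone), such as the calprotectin subunit S100a9 (4.45 ± 1.33, adjusted p = 0.0495) and the neutrophil gene Retnlg (4.07 ± 0.80). Their median was 2.49, or 2.35 with the slide as a block and 1.95 within slide 5 (camera adjusted p = 1.2e-09, adjusted p = 0.232 with an estimated correlation). Chemokines rose in 8 of 21 cases and fell in 1 (9 and 1 adjusted over the list alone), led after Cxcl10 by Ccl4 (6.31 ± 1.07) and the neutrophil attractant Cxcl2 (5.85 ± 1.39). Their median was 1.32, or 1.55 with the slide as a block and 1.99 within slide 5 (camera adjusted p = 1.57e-05, adjusted p = 0.307 with an estimated correlation).

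Genes of MHC class I presentation rose in 6 of 18 cases (12 adjusted over the list alone), among them the peptide transporter Tap1 (2.58 ± 0.37) and the immunoproteasome subunit Psmb8 (1.66 ± 0.31). Their median was 0.79, or 0.67 with the slide as a block and 0.58 within slide 5 (camera adjusted p = 3.73e-07, adjusted p = 0.193 with an estimated correlation). Of 16 genes of endothelial activation, 9 rose, a count that was 9 adjusted over the list alone. The adhesion molecules Selp (3.69 ± 0.54) and Icam1 (3.03 ± 0.88) were among them. Their median was 2.11, or 2.20 with the slide as a block and 2.17 within slide 5 (camera adjusted p = 5.16e-07, adjusted p = 0.22 with an estimated correlation). Cholesterol biosynthesis had 4 of 18 genes lower (6 adjusted over the list alone), with the enzymes Mvd (-2.85 ± 0.51) and Sc5d (-3.81 ± 1.01) as examples. Their median was -0.90, or -1.04 with the slide as a block and -0.58 within slide 5 (camera adjusted p = 0.000386, adjusted p = 0.544 with an estimated correlation). Bile acid synthesis and transport had 2 of 24 genes lower (2 adjusted over the list alone), Cyp7a1 and the hepatocyte bile acid importer Slc10a1 (-2.74 ± 0.76). Their median was -0.67, or -0.38 with the slide as a block and -0.13 within slide 5 (camera adjusted p = 0.0474, adjusted p = 0.809 with an estimated correlation). For cytochrome P450 and drug metabolism the median of 32 genes was -0.38, with 2 lower, 0 adjusted over the list alone, and a camera adjusted p = 0.131. Acute phase proteins had 1 of 24 genes past the threshold and 0 adjusted over the list alone. Their median was 0.59, or 0.55 with the slide as a block and 0.35 within slide 5 (camera adjusted p = 0.0021, adjusted p = 0.778 with an estimated correlation). Their best known members had large values and errors beside sham replicate 3 and 24 h replicate 3, and lay near the signal's ceiling at 6 h, Saa3 5.28 ± 2.19 (adjusted p = 0.135) and Lcn2, an iron-sequestering protein, 3.59 ± 1.69 (adjusted p = 0.183).

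In all, 1251 of 10298 genes passed in liver at 6 h, 584 higher and 667 lower, and the median of all genes was -0.09. The count was 303 without sham replicate 1, 236 without sham replicate 2, 689, 629 and 721 without 6 h replicates 1, 3 and 4, and 766 with the slide as a block, where slide 5 alone holds sham and PCI arrays. With that block Dbp, Gbp2, Cd14, Tlr2, Socs3, S100a9, Retnlg, Psmb8 and Icam1 did not pass. It was 1864 without liver sham replicate 3 and liver 24 h replicate 3 together.

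At 24 h the liver arrays showed medians above sham for neutrophil markers and below sham for hepatic metabolism, while no single gene passed. The 17 neutrophil markers had a median of 1.46, or 1.13 with the slide as a block and 1.39 within slide 5 (camera adjusted p = 9.09e-07, adjusted p = 0.568 with an estimated correlation), and 0 of them passed, over all genes or adjusted over the list alone. Genes of cytochrome P450 and drug metabolism, which detoxify drugs and hormones, had a median of -0.81, or -0.87 with the slide as a block and -1.33 within slide 5 (camera adjusted p = 6.47e-07, adjusted p = 0.568 with an estimated correlation), with 1 of 32 higher and 3 lower adjusted over the list alone. Cholesterol biosynthesis stood at -0.66, or -0.49 with the slide as a block and -1.02 within slide 5 (camera adjusted p = 3.72e-05, adjusted p = 0.568 with an estimated correlation). Fatty acid and triglyceride synthesis stood at -0.69, or -0.83 with the slide as a block and -0.96 within slide 5 (camera adjusted p = 1.72e-05, adjusted p = 0.568 with an estimated correlation). In either list 0 members passed, over all genes or adjusted over the list alone. Endoplasmic reticulum stress genes had a median of 0.71, or 0.50 with the slide as a block and 0.86 within slide 5 (camera adjusted p = 5.16e-06, adjusted p = 0.568 with an estimated correlation) over 25 genes, 0 of them past adjusted over the list alone. Interferon-stimulated genes were near the sham level, with a median of -0.13 (camera adjusted p = 0.48), and Cxcl10 differed from sham by 0.72 ± 0.82 (adjusted p = 0.81).

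Among 15 genes followed in every comparison, a panel of acute phase and cytokine genes, all 15 had positive values in liver at 24 h and 0 passed, from 0.06 for the transcription factor Stat3 to 3.26 for Saa3 (SE 2.19; 1.93 to 5.90 without 1 array, the highest without sham replicate 3). Of 10298 genes, limma called 0, 838 had an unadjusted p under 0.05 against 515 expected by chance, and the smallest adjusted p was 0.175. The count was 123 without 24 h replicate 3, the array with Saa3 at the sham level, 1 without sham replicate 3, 558 without both, and 2821 when limma weighted the arrays by their fit.

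At 6 h the lung showed large rises of chemokines beside interferon-induced, neutrophil and endothelial changes. Cxcl10 rose 272-fold (log2 8.09 ± 0.68, adjusted p = 0.000301; 7.76 with the slide as a block and 7.51 within slide 5). Saa3 rose 54.3-fold (log2 5.76 ± 1.36, adjusted p = 0.0194), and Acod1, which makes the antibacterial metabolite itaconate in macrophages, rose by 6.42 ± 1.04. The ligand Wnt3a fell by 4.01 ± 0.66 (adjusted p = 0.00528), Wnt7a fell by 3.40 ± 0.52, and Calcrl, an endothelial receptor for adrenomedullin, fell by 3.54 ± 0.89.

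Interferon-stimulated genes rose in 32 of 34 cases (33 adjusted over the list alone), for example Oasl1 (4.83 ± 0.54), Rsad2 (4.69 ± 0.45) and the antiviral GTPase Mx2 (4.65 ± 0.69). Their median was 2.45, or 2.13 with the slide as a block and 1.92 within slide 5 (camera adjusted p = 5.34e-31, adjusted p = 0.312 with an estimated correlation). Chemokines rose in 14 of 23 cases and fell in 1 (16 and 1 adjusted over the list alone), including Cxcl2 (7.17 ± 1.49), Ccl3 (6.42 ± 1.14) and Ccl4 (6.05 ± 0.75). Their median was 2.48, or 2.45 with the slide as a block and 2.20 within slide 5 (camera adjusted p = 1.36e-09, adjusted p = 0.312 with an estimated correlation). Neutrophil markers rose in 17 of 21 cases, 17 adjusted over the list alone. Retnlg (4.24 ± 0.70), the lectin Clec4d (4.34 ± 0.92) and S100a8 (2.75 ± 0.66) are examples. Their median was 2.63, or 2.17 with the slide as a block and 2.20 within slide 5 (camera adjusted p = 2.54e-11, adjusted p = 0.312 with an estimated correlation). Granule genes of neutrophil precursors rose in 7 of 16 cases (9 adjusted over the list alone), among them Ngp (5.66 ± 0.98), myeloperoxidase Mpo (5.35 ± 1.25) and the antimicrobial peptide gene Camp (4.96 ± 0.96). Their median was 1.40, or 1.68 with the slide as a block and 1.66 within slide 5 (camera adjusted p = 1.31e-05, adjusted p = 0.36 with an estimated correlation). Acute phase proteins rose in 8 of 22 cases (12 adjusted over the list alone), with Saa1 (5.05 ± 1.05) after Saa3. Their median was 1.38, or 1.18 with the slide as a block and 1.31 within slide 5 (camera adjusted p = 4.36e-06, adjusted p = 0.324 with an estimated correlation). Among cytokines, 8 of 22 rose (9 higher and 1 lower adjusted over the list alone), including Tnf (3.75 ± 0.82), Osm (3.75 ± 0.92) and Il1b (3.35 ± 0.85). Their median was 0.94, or 0.96 with the slide as a block and 0.81 within slide 5 (camera adjusted p = 0.000753, adjusted p = 0.312 with an estimated correlation).

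Of 16 endothelial activation genes 12 rose (13 higher and 2 lower adjusted over the list alone), such as the adhesion molecule Selp (5.17 ± 1.01) and Ackr1, a chemokine receptor of venules (5.45 ± 0.74). Their median was 1.59, or 1.38 with the slide as a block and 1.46 within slide 5 (camera adjusted p = 1.26e-06, adjusted p = 0.312 with an estimated correlation). Genes of endothelial identity went both ways, 3 higher and 6 lower of 25 (4 and 11 adjusted over the list alone). The lower ones include the transcription factor Sox18 (-3.17 ± 0.90), the angiopoietin receptor Tek (-2.26 ± 0.56) and Ramp2, the partner of Calcrl (-2.22 ± 0.50), and camera did not call the list (median -0.75, adjusted p = 0.149). Cell cycle genes rose in 13 of 31 cases (17 adjusted over the list alone), with the mitotic genes Birc5 (1.68 ± 0.27), Top2a (1.59 ± 0.23) and Cdk1 (1.52 ± 0.29) as examples. Their median was 0.64, or 0.99 with the slide as a block and 0.80 within slide 5 (camera adjusted p = 1.61e-08, adjusted p = 0.312 with an estimated correlation). Cholesterol biosynthesis had 7 of 18 genes lower and 1 higher (7 and 1 adjusted over the list alone), with Dhcr7 (-1.63 ± 0.29) and Fdps (-1.44 ± 0.24) lower, Pmvk (2.88 ± 0.52) higher. Their median was -0.63, or -0.73 with the slide as a block and -0.52 within slide 5 (camera adjusted p = 0.00136, adjusted p = 0.312 with an estimated correlation). Of the 15 panel genes 13 passed, all higher, and Il6 (at least 4.06-fold higher, adjusted p = 0.0919) and Il10 (at least 11.5-fold higher, adjusted p = 0.0516) did not, neither being above background in any sham array. The adipose and muscle lists had no member past at 6 h, and their medians turned from -0.52 and -0.40 to 0.36 and 0.70 with the slide as a block (0.94 and 1.31 within slide 5). Transcripts of these tissues varied within the sham group, the median muscle gene at a log2 intensity of 13.28 in sham replicate 1 against 9.17 and 10.63 in the others.

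In lung at 6 h 2044 of 11888 genes passed, 1023 higher and 1021 lower. The count was 647 without sham replicate 1, 442 without sham replicate 2, 903, 866 and 1113 without 6 h replicates 1, 3 and 4, and 1781 with the slide as a block, where Saa3, Saa1, S100a8 and Il1b did not pass.

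At 24 h a pair of clock genes passed in lung, and neutrophil and cell cycle genes stood above sham as groups. Arntl, the core clock activator also called Bmal1, rose 5.58-fold (log2 2.48 ± 0.31, adjusted p = 0.0321), and the clock output gene Dbp fell by 3.99 ± 0.41 (adjusted p = 0.0117), while the labels give no time of day for any group. The 14 circadian clock genes had a median of -0.73, or -1.16 with the slide as a block and -1.01 within slide 5 (camera adjusted p = 0.0108, adjusted p = 0.326 with an estimated correlation), with 2 higher and 7 lower adjusted over the list alone. Neutrophil markers had a median of 2.14, or 1.61 with the slide as a block and 1.30 within slide 5 (camera adjusted p = 5.82e-16, adjusted p = 0.228 with an estimated correlation), 13 of 21 higher adjusted over the list alone and 0 over all genes. Cell cycle genes stood at 0.56, or 0.68 with the slide as a block and 0.74 within slide 5 (camera adjusted p = 5.82e-16, adjusted p = 0.228 with an estimated correlation), with 17 of 31 higher adjusted over the list alone.

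Chemokines (11 of 23 higher adjusted over the list alone) had a median of 1.22, or 0.87 with the slide as a block and 1.03 within slide 5 (camera adjusted p = 4.75e-08, adjusted p = 0.267 with an estimated correlation). Acute phase proteins (6 of 22 higher adjusted over the list alone) had one of 1.25, or 0.97 with the slide as a block and 0.62 within slide 5 (camera adjusted p = 9.9e-08, adjusted p = 0.28 with an estimated correlation). Liver transcripts differed among these arrays, with 21 and 20 of the 26 hepatocyte secreted proteins detected in 24 h replicate 3 and sham replicate 1 and 10 to 17 in the other lung arrays. MHC class II presentation, by which helper T cells are shown antigen, had 7 of 10 genes lower adjusted over the list alone. Their median was -0.64, or -0.43 with the slide as a block and -0.32 within slide 5 (camera adjusted p = 5.38e-06, adjusted p = 0.302 with an estimated correlation). Adipose and muscle genes, whose tissues adjoin the lung, had medians of -1.0 (camera adjusted p = 0.0224, adjusted p = 0.507 with an estimated correlation) and -0.88 (camera adjusted p = 0.00704, adjusted p = 0.528 with an estimated correlation). With the slide as a block they were -0.14 and 0.23, within slide 5 -0.94 and -0.39, and the muscle median was 0.01 without lung sham replicate 1. Saa3 differed from sham by 5.50 ± 1.36 (adjusted p = 0.159; 4.23 to 7.87 without 1 array), Cxcl10 by 2.69 ± 0.68 (adjusted p = 0.178) and S100a8 by 2.54 ± 0.66 (adjusted p = 0.186), and 0 of the 15 panel genes passed. Of 11888 genes limma called 2 and 1411 had an unadjusted p under 0.05, against 594 expected by chance. The count was 0 without sham replicate 1, sham replicate 2 or 24 h replicate 2, and 0 with the slide as a block. It was 69 without sham replicate 3, 49 without 24 h replicate 1 and 13 without 24 h replicate 3.

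At 6 h the spleen showed rises of chemokines, cytokines and interferon-induced genes beside falls of T cell markers and of Clec9a and Mycl. Cxcl2 rose by 6.78 ± 1.40 (adjusted p = 0.0059) and Cxcl10 rose 23-fold (log2 4.52 ± 0.57; 4.15 with the slide as a block and 4.25 within slide 5). Il6, a cytokine that drives the acute phase response, was above background in no sham array and at least 15.5-fold higher at 6 h (adjusted p = 0.00287), and the pattern recognition protein Ptx3 at least 25-fold higher. Clec9a, a receptor of cross-presenting dendritic cells, fell between log2 intensity means ± SD of 9.08 ± 0.66 and 5.85 ± 0.31 in sham and PCI (adjusted p = 0.000328), and Mycl, a transcription factor of dendritic cells, fell by 4.26 ± 0.46. The chemokine receptor Cx3cr1 fell by 3.54 ± 0.62 and the iron exporter Slc40a1 fell by 2.98 ± 0.61.

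Interferon-stimulated genes rose in 31 of 34 cases (33 adjusted over the list alone), such as Oasl1 (4.00 ± 0.46) and Isg15 (3.86 ± 0.47). Their median was 2.12, or 1.92 with the slide as a block and 1.76 within slide 5 (camera adjusted p = 1.32e-25, adjusted p = 0.387 with an estimated correlation). Chemokines rose in 12 of 22 cases and fell in 1 (12 and 2 adjusted over the list alone), including Cxcl1 (5.39 ± 1.15) and Ccl4 (5.08 ± 0.64). Their median was 1.23, or 1.19 with the slide as a block and 1.28 within slide 5 (camera adjusted p = 8.68e-06, adjusted p = 0.412 with an estimated correlation). Of 24 cytokines 12 rose and 2 fell (14 and 2 adjusted over the list alone), with Il10 (4.24 ± 0.57) and Il1rn, the natural blocker of interleukin 1 (5.15 ± 0.95), among the higher. Their median was 1.14, or 0.98 with the slide as a block and 0.94 within slide 5 (camera adjusted p = 5.46e-05, adjusted p = 0.412 with an estimated correlation). Negative feedback regulators rose in 15 of 23 cases (16 adjusted over the list alone), Socs3 by 2.87 ± 0.48. Their median was 1.48, or 1.48 with the slide as a block and 1.40 within slide 5 (camera adjusted p = 4.48e-08, adjusted p = 0.412 with an estimated correlation). Genes of the oxidative stress response rose in 8 of 23 cases (8 adjusted over the list alone). Their median was 0.21, or 0.71 with the slide as a block and 1.05 within slide 5 (camera adjusted p = 0.00311, adjusted p = 0.387 with an estimated correlation).

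T cell markers fell in 14 of 25 cases and rose in 2 (17 and 2 adjusted over the list alone). Thy1 (-2.95 ± 0.48) and Cd27 (-2.02 ± 0.32) were lower, the checkpoint receptor Ctla4 (3.00 ± 0.77) and the homing receptor Ccr7 (2.11 ± 0.63) higher. Their median was -0.81, or -0.85 with the slide as a block and -0.80 within slide 5 (camera adjusted p = 0.000316, adjusted p = 0.412 with an estimated correlation). MHC class II presentation had 5 of 10 genes lower (7 adjusted over the list alone), including its master regulator Ciita (-1.46 ± 0.35) and H2-DMb2 (-1.15 ± 0.24). Their median was -0.89, or -0.58 with the slide as a block and -0.44 within slide 5 (camera adjusted p = 0.00959, adjusted p = 0.652 with an estimated correlation). B cell markers had 4 of 19 lower and 1 higher (8 and 1 adjusted over the list alone), with the B cell receptor for IgE Fcer2a (-2.60 ± 0.53) among the lower, and camera did not call the list (median -0.52, adjusted p = 0.0803). Cholesterol biosynthesis had 9 of 17 genes lower and 1 higher (10 and 1 adjusted over the list alone), such as Lss (-1.54 ± 0.45) and Dhcr7 (-1.25 ± 0.32), and was not called by camera either (median -0.83, adjusted p = 0.0527). Erythroid genes had 1 of 22 past, the haemoglobin gene Hbb-b2 (2.49 ± 0.72), 0 adjusted over the list alone. Their median was 1.21, or 2.10 with the slide as a block and 2.71 within slide 5 (camera adjusted p = 0.00182, adjusted p = 0.761 with an estimated correlation). The 15 panel genes included 11 past, all higher. Saa3 (4.55 ± 1.27), Lcn2 (2.70 ± 0.90) and Il1b (1.87 ± 0.54) passed although their PCI arrays overlapped the sham arrays. Pancreas transcripts, from the organ that adjoins the spleen, were detected for all 20 genes of the list in spleen sham replicate 1, 6 h replicates 1 and 2 and 24 h replicates 1 and 4. The list's median was 0.79 at 6 h (camera adjusted p = 0.392; 0.48 with the slide as a block and 2.45 within slide 5) and 0.91 at 24 h (camera adjusted p = 0.461; -1.29 and -3.04).

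In spleen at 6 h 2988 of 11147 genes passed, 1148 higher and 1840 lower. The count was 1313 without sham replicate 2, 1954 without sham replicate 3, and 2446 with the slide as a block, where Il1rn, Lss, Dhcr7, Hbb-b2, Saa3, Lcn2 and Il1b did not pass.

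At 24 h the spleen still had 639 genes past the threshold, among them lower antigen presentation and T cell genes and a few higher respiration and chaperone genes. Saa3 rose 79.4-fold (log2 6.31 ± 1.27, adjusted p = 0.02; 5.84 with the slide as a block and 5.93 within slide 5). The monocyte chemokine Ccl12 rose 23.3-fold (log2 4.54 ± 0.35, adjusted p = 0.00026) and Il10 rose by 3.60 ± 0.57 (adjusted p = 0.00995). Clec9a was above background in all 3 sham arrays and in no 24 h array, at least 11.1-fold lower, and Mycl fell by 3.92 ± 0.46. Arg1, the arginase of alternatively activated macrophages, rose by 2.59 ± 0.48, and the scavenger receptor Marco rose by 2.12 ± 0.32.

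MHC class II presentation fell in 8 of 10 genes (all 10 adjusted over the list alone), including H2-Eb1 (-1.15 ± 0.15), H2-Ab1 (-1.10 ± 0.19) and Ciita (-1.47 ± 0.35). Their median was -1.09, or -0.73 with the slide as a block and -0.84 within slide 5 (camera adjusted p = 1.11e-08, adjusted p = 0.357 with an estimated correlation). T cell markers fell in 11 of 25 cases (17 adjusted over the list alone), among them the receptor chain Cd3e (-1.16 ± 0.22), Cd27 (-1.25 ± 0.32) and the T cell transcription factor Bcl11b (-1.22 ± 0.27). Their median was -0.86, or -0.87 with the slide as a block and -0.90 within slide 5 (camera adjusted p = 1.22e-08, adjusted p = 0.341 with an estimated correlation). Oxidative phosphorylation rose in 6 of 55 genes (13 adjusted over the list alone), such as Cox7b (1.5 ± 0.27) and Sdhd (1.46 ± 0.31). Their median was 0.35, or 0.45 with the slide as a block and 0.46 within slide 5 (camera adjusted p = 3.13e-11, adjusted p = 0.341 with an estimated correlation). Cell cycle genes had 2 of 33 higher over all genes and 23 adjusted over the list alone, with the replication factors Pcna (1.43 ± 0.21) and Mcm7 (1.21 ± 0.29) as examples. Their median was 1.21, or 1.76 with the slide as a block and 1.80 within slide 5 (camera adjusted p = 1.11e-12, adjusted p = 0.439 with an estimated correlation). Heat shock proteins rose in 4 of 20 cases (6 adjusted over the list alone), for example Hsp90aa1 (1.41 ± 0.27) and Hspe1 (1.45 ± 0.37). Their median was 0.36, or 0.54 with the slide as a block and 0.41 within slide 5 (camera adjusted p = 8.98e-05, adjusted p = 0.414 with an estimated correlation). Interferon-stimulated genes had 3 of 34 higher (17 adjusted over the list alone), including Isg15 (2.13 ± 0.47) and Irf7 (1.79 ± 0.28). Their median was 0.73, or 0.41 with the slide as a block and 0.62 within slide 5 (camera adjusted p = 5.3e-09, adjusted p = 0.433 with an estimated correlation). Neutrophil markers had 3 of 20 higher (13 adjusted over the list alone), such as Cd177 (1.94 ± 0.50). Their median was 1.43, or 1.76 with the slide as a block and 1.52 within slide 5 (camera adjusted p = 9.73e-08, adjusted p = 0.433 with an estimated correlation).

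In spleen at 24 h 639 of 11147 genes passed, 301 higher and 338 lower, and 3 of the 15 panel genes, Saa3, Il10 and the monocyte chemokine Ccl2 (2.23 ± 0.57, with overlapping arrays). The count was 24 without sham replicate 2, 152 without sham replicate 3, 207, 243 and 1219 without 24 h replicates 1, 2 and 4, and 107 with the slide as a block. With that block Saa3, Marco, Ccl2 and, of the genes named from the lists, all but Cox7b and Pcna did not pass.

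In blood at 6 h few genes passed, among them 6 interferon-stimulated genes. Cxcl10 rose 17.5-fold (log2 4.13 ± 0.57, adjusted p = 0.0438; 3.56 with the slide as a block and 3.76 within slide 5). Ifng, the cytokine interferon gamma, rose by 3.09 ± 0.48, Tnfrsf9, a receptor induced on activated T cells and NK cells, by 3.12 ± 0.56, and the chemokine-binding receptor Ccrl2 by 4.12 ± 0.77, each with an adjusted p of 0.0438. S1pr5, a receptor that lets NK cells leave the tissues, fell by 2.32 ± 0.42, the phosphatase gene Ptpro fell by 2.99 ± 0.55 and the microtubule protein gene Tppp3 fell by 2.69 ± 0.35.

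Interferon-stimulated genes rose in 6 of 34 cases (19 adjusted over the list alone), for example Oasl1 (3.58 ± 0.58), Ifit3 (3.06 ± 0.57) and Gbp2 (3.1 ± 0.57). Their median was 1.38, or 0.80 with the slide as a block and 1.13 within slide 5 (camera adjusted p = 1.59e-19, adjusted p = 0.119 with an estimated correlation). Cytokines had 1 of 20 past, Ifng, and 4 higher adjusted over the list alone. Their median was 0.84, or 1.02 with the slide as a block and 1.21 within slide 5 (camera adjusted p = 1.64e-05, adjusted p = 0.0441 with an estimated correlation). Chemokines, cell cycle genes and lung epithelium genes had 1 member each past the threshold, and the other lists none. Negative feedback regulators had 12 of 22 higher adjusted over the list alone. Their median was 1.97, or 1.30 with the slide as a block and 1.58 within slide 5 (camera adjusted p = 5.86e-10, adjusted p = 0.382 with an estimated correlation). Granule genes of neutrophil precursors had 10 of 15 higher adjusted over the list alone. Their median was 1.86, or 1.30 with the slide as a block and 2.45 within slide 5 (camera adjusted p = 8.46e-08, adjusted p = 0.382 with an estimated correlation). MHC class II presentation had 3 of 10 lower adjusted over the list alone. Their median was -1.62, or -0.73 with the slide as a block and -1.72 within slide 5 (camera adjusted p = 5.18e-05, adjusted p = 0.589 with an estimated correlation).

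Liver transcripts were present in 4 blood arrays, with 24 and 19 of the 26 hepatocyte secreted proteins detected in 6 h replicates 1 and 2 and 20 and 21 in 24 h replicates 1 and 4, against 1 to 5 in 6 other arrays and 11 in sham replicate 1. Beside them, acute phase proteins at 6 h had 0 members past and a median of 3.04, or 2.33 with the slide as a block and 4.64 within slide 5 (camera adjusted p = 8.46e-08, adjusted p = 0.589 with an estimated correlation). Hepatocyte secreted proteins had one of 2.15, or 2.48 with the slide as a block and 4.06 within slide 5 (camera adjusted p = 4.08e-05, adjusted p = 0.639 with an estimated correlation). Complement genes stood at 1.49, or 1.35 with the slide as a block and 1.86 within slide 5 (camera adjusted p = 6.96e-05, adjusted p = 0.628 with an estimated correlation). Cytochrome P450 genes, which belong to the liver, stood at 1.36, or 1.79 with the slide as a block and 2.38 within slide 5 (camera adjusted p = 0.00342, adjusted p = 0.701 with an estimated correlation). In each of these 4 lists 0 members passed adjusted over the list alone. Of the 15 panel genes Cxcl10 alone passed, and Saa3 (4.81 ± 1.61, adjusted p = 0.166) and Il10 (3.25 ± 1.18, adjusted p = 0.191) did not. In blood at 6 h 41 of 9223 genes passed, 29 higher and 12 lower, and 1573 had an unadjusted p under 0.05 against 461 expected by chance. The count was 162 without sham replicate 1, 1 without sham replicate 2, 2 without 6 h replicate 1, 1 without 6 h replicate 3 and 0 without sham replicate 3, 6 h replicate 2 or 6 h replicate 4, and it was 0 with the slide as a block or with all 44 arrays normalized together.

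At 24 h the blood arrays showed a higher median for cell cycle genes and lower medians for lymphocyte and antigen presentation genes, with no gene past the threshold. Cell cycle genes had 1 of 31 higher adjusted over the list alone. Their median was 0.87, or 0.64 with the slide as a block and 0.24 within slide 5 (camera adjusted p = 1.95e-20, adjusted p = 0.569 with an estimated correlation). T cell markers stood at -0.68, or -0.25 with the slide as a block and 0.58 within slide 5 (camera adjusted p = 8.23e-06, adjusted p = 0.569 with an estimated correlation) over 24 genes. MHC class II presentation stood at -1.35, or -0.31 with the slide as a block and 0.39 within slide 5 (camera adjusted p = 1.05e-07, adjusted p = 0.569 with an estimated correlation) over 10 genes. B cell markers had a median of -0.99, or 0.00 with the slide as a block and 1.09 within slide 5 (camera adjusted p = 1.42e-06, adjusted p = 0.569 with an estimated correlation). Acute phase proteins, beside the liver transcripts in 24 h replicates 1 and 4, stood at 2.03, or 0.83 with the slide as a block and -0.98 within slide 5 (camera adjusted p = 3.75e-06, adjusted p = 0.569 with an estimated correlation). Within slide 5, where the raised array is 1 of 2 sham arrays, the last 4 medians turned in sign, the B cell one also with the slide as a block. No member of these 4 lists passed when adjusted over the list alone. Saa3 differed from sham by 4.68 ± 1.61 (adjusted p = 0.971), and by 2.47 to 7.35 without 1 array, the highest without sham replicate 1. Of 9223 genes limma called 0, 309 had an unadjusted p under 0.05 against 461 expected by chance, and the smallest adjusted p was 0.971. The count was 1 without sham replicate 1.

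**Figure D2:**
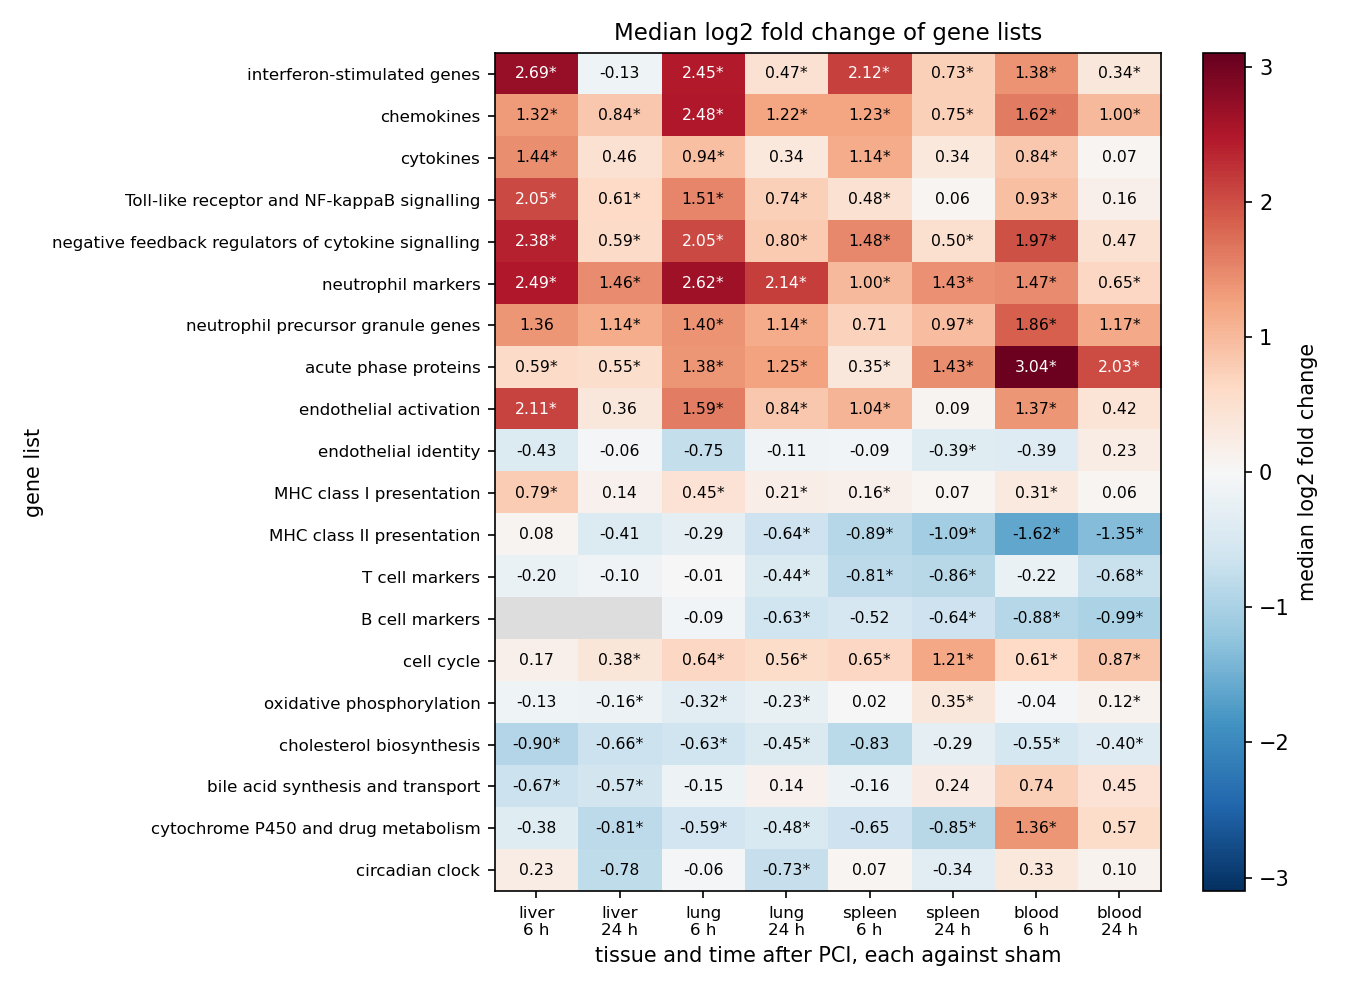
Median log2 fold change of the tested members of 20 gene lists (y axis) for each tissue and time against sham (x axis). An asterisk marks a camera adjusted p under 0.05 with the preset correlation, for example interferon-stimulated genes at 6 h with 2.69 in liver, and grey marks lists with too few tested genes.

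Chemokine and interferon-induced genes were among those lower at 24 h than at 6 h, Cxcl10 in every tissue. Cxcl10 fell by 6.13 ± 0.76 in liver (adjusted p = 0.00127), by 5.4 ± 0.63 in lung (adjusted p = 0.0022), by 2.86 ± 0.52 in spleen (adjusted p = 0.00932) and by 4.11 ± 0.53 in blood (adjusted p = 0.0153). In liver Ifit2 fell by 5.86 ± 0.43 and Rsad2 fell by 5.57 ± 0.58, while G0s2 rose by 5.07 ± 0.42 (adjusted p = 0.000108) and Hhex, a hepatocyte transcription factor, by 3.24 ± 0.67. In lung Il1rn fell by 3.61 ± 0.81 and Oasl1 fell by 3.60 ± 0.50, while Wnt3a rose by 2.82 ± 0.61 and Wnt7a by 2.36 ± 0.48. In spleen Ptx3 fell by 4.35 ± 0.67 and the collagenase gene Mmp13 fell by 4.71 ± 0.62, while Arg1 rose by 3.30 ± 0.45 (adjusted p = 0.00321) and the neutrophil protease gene Mmp9 by 2.48 ± 0.55. In blood Ifng fell by 3.02 ± 0.44 and Mx1 fell by 2.82 ± 0.38, while Tppp3 rose by 3.45 ± 0.33 (adjusted p = 0.00185).

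For these genes all 4 arrays of one time lay on one side of all 4 of the other. In liver, lung and blood slides 1, 3 and 5 hold arrays of both times, and within them the change of Cxcl10 was -4.70, -8.57 and -7.54 in liver, -5.02, -7.85 and -5.52 in lung, and -3.86, -4.97 and -4.91 in blood. Between the times 844 genes passed in liver (428 higher at 24 h, 416 lower), 582 in lung (280 and 302), 1284 in spleen (724 and 560) and 15 in blood (4 and 11). With the slide as a block, which drops the lone 24 h array of slide 2, the counts were 2467, 4101, 3777 and 77. In each tissue this array stood close to the 6 h arrays on an axis of 200 genes, in blood beside 24 h replicate 1. Its interferon-stimulated genes did not. With it alone left out (24 h replicate 1 in liver and lung, 4 in spleen and blood) the counts were 3096, 4370, 3714 and 333. Both sets leave out the same array. In liver the count was 352 and 329 without 24 h replicates 2 and 4, and 332, 339 and 514 without 6 h replicates 1, 3 and 4. In lung it was 149, 172 and 179 without 24 h replicates 2, 3 and 4, and 180, 385, 173 and 218 without 6 h replicates 1 to 4. In spleen it was 453, 491 and 493 without 24 h replicates 1, 2 and 3, and 754, 751 and 628 without 6 h replicates 1, 2 and 4. In blood it was 5, 1, 6 and 1 without 6 h replicates 1 to 4, and 1, 4 and 2 without 24 h replicates 1, 2 and 3.

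**Figure D3:**
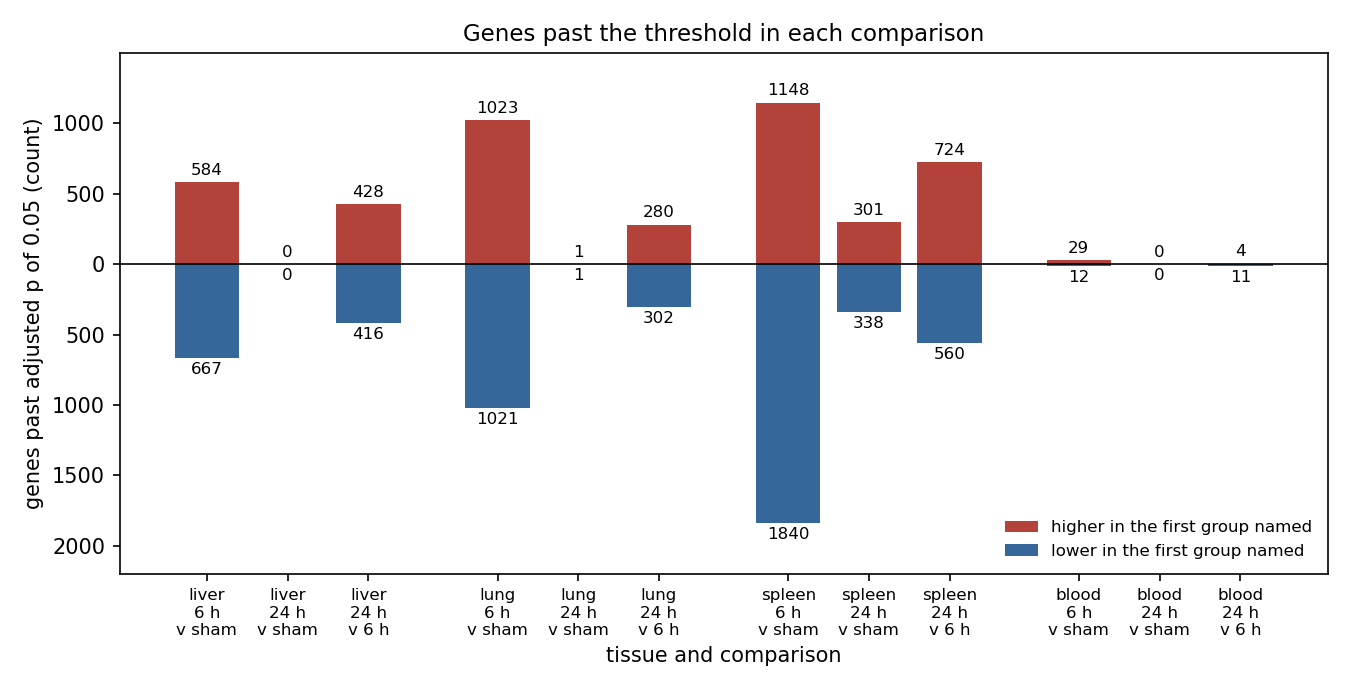
Number of genes past an adjusted p of 0.05 (y axis) in each tissue and comparison (x axis), higher above and lower below 0. Spleen at 6 h has 1148 higher and 1840 lower, and liver and blood at 24 h against sham have 0.

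At 6 h 16 genes changed the same way in all 4 tissues, 15 higher and 1 lower of 8120 tested in each. Cxcl10 rose 115-fold in liver, 272-fold in lung, 23-fold in spleen and 17.5-fold in blood. The antiviral genes Oasl1 (3.58 to 4.83 over the tissues), Ifit3 (2.44 to 3.90), Ifit2 (1.68 to 5.92) and Mx1 (2.25 to 4.11) rose in all 4, as did Gbp2 (1.95 to 4.53), the lipid scramblase gene Plscr1 (1.60 to 3.81), the ADP-ribosyltransferase gene Parp10 (1.63 to 2.07), the co-repressor Daxx (2.16 to 2.59) and Tnfrsf9 (2.16 to 3.35). Mx1 in liver and lung and Tnfrsf9 in liver were above background in no sham array, at least 13-fold, 7.57-fold and 3.06-fold higher. Tmem86a, a lysoplasmalogenase, fell in all 4, with values from -2.89 in spleen to -1.21 in lung.

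For lists of independent genes 0.0186 higher and 0.00743 lower genes would be shared by all 4 tissues. The count was 0 without any single blood 6 h array, without blood sham replicate 2 or without blood sham replicate 3, and 69 without blood sham replicate 1. It was 10 without liver sham replicate 2, 0 with the slide as a block and 73 without the raised sham arrays and liver 24 h replicate 3. Over liver, lung and spleen alone, a set chosen after the count in blood was seen, 366 of 9302 genes changed the same way, 217 higher and 149 lower, against 5.44 and 8.65 for independent lists. The higher ones hold 25 interferon-stimulated genes, 10 negative feedback regulators, 9 genes of Toll-like receptor and NF-kappaB signalling, 7 chemokines and 6 neutrophil markers, and the lower ones hold 3 of endothelial identity, a list with 2 among the higher, and 2 of cholesterol biosynthesis. At 24 h limma called 0 genes in all 4 tissues, and 1 without those arrays.

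**Figure D4:**
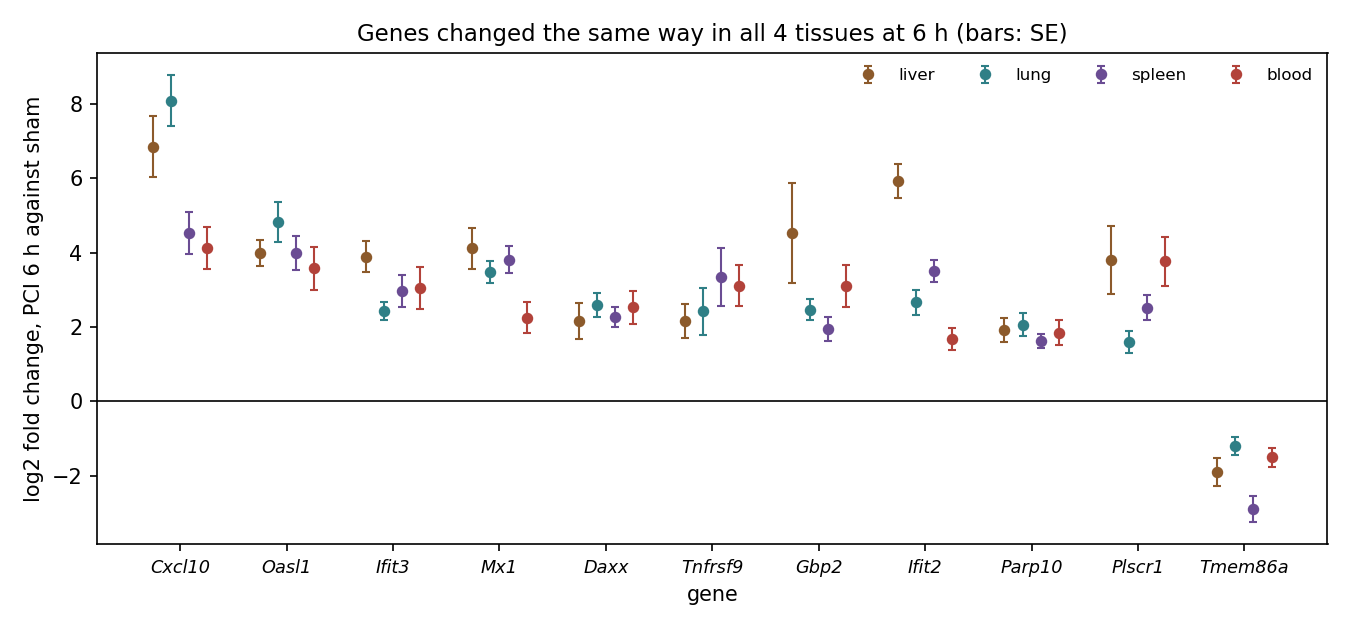
Log2 fold change at 6 h against sham with SE (y axis) in each tissue for the 11 named genes (x axis) that passed in all 4 tissues. Cxcl10 has the largest values, 8.09 in lung, and Tmem86a is the single gene that is lower.

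Across all 8120 genes Pearson's r between the changes at 6 h (across genes, which are not independent replicates) was 0.687 for liver and lung, 0.674 for lung and spleen, 0.595 for lung and blood, 0.584 for liver and spleen, 0.569 for spleen and blood and 0.508 for liver and blood. Of the genes past in both tissues of a pair or in 1 of them, 81.8% to 88.0% had the same sign. At 24 h the 6 values of r were 0.466, 0.401, 0.422, 0.322, 0.408 and 0.223 in the same order. Arrays at the same place of the slide layout went together between tissues (mean correlation 0.204 with group means removed), so the tissues are not independent, which the F test and the counts for independent lists leave out. Without any change, splits of the places, with group means removed, gave a mean r of 0.147 and at most 0.413 at 6 h, and 0.292 and at most 0.622 at 24 h, so the values at 24 h lie within what shared places give. Within a tissue the changes at 6 h and 24 h share their sham arrays, and r between the times was 0.579 in liver, 0.730 in lung, 0.687 in spleen and 0.631 in blood, where simulated arrays without any change gave 0.572, 0.568, 0.574 and 0.572. The covariances were 0.281, 0.291, 0.319 and 0.256, and the simulated ones 0.0879, 0.0582, 0.0634 and 0.126. In spleen 171 genes were higher and 253 lower at both times and 1 was opposite, against 31.0 and 55.8 for independent lists. With 3 sham arrays per tissue the controls were not split, and part of this excess may come from the shared controls.

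Some responses differed between tissues at 6 h. G0s2 fell in liver (-4.17 ± 0.46) and lung (-2.48 ± 0.25) and had a value of 1.47 ± 0.63 in blood (F test of the tissue difference, adjusted p = 7.96e-06). Rsad2 was raised by 5.50 ± 0.63 in liver, 4.69 ± 0.45 in lung and 3.16 ± 0.38 in spleen and had a value of 0.21 ± 0.22 in blood (adjusted p = 1.56e-05). Thbd, the anticoagulant receptor thrombomodulin, had values of 2.06 ± 0.69 in liver, 1.26 ± 0.23 in spleen, -1.30 ± 0.35 in lung and -2.33 ± 0.47 in blood (adjusted p = 0.000257). The lymphoid chemokine Ccl19 had values of 2.29 ± 0.34 and 3.05 ± 0.44 in liver and lung and -1.39 ± 0.26 in spleen (adjusted p = 0.000525). Ackr1 (5.45 ± 0.74) and Tmem252 (4.88 ± 0.86) had their highest values in lung, and Tlr2 (5.77 ± 1.10) its highest in liver (adjusted p = 0.00346, 0.00212 and 0.0212). Ptx3 reached 5.70 ± 1.02 in lung and was at least 25-fold higher in spleen, while in liver 0 sham arrays and 2 of the 4 arrays at 6 h were above background (adjusted p = 0.0153). The protease gene Adamts4 was at least 27.4-fold higher in lung, while in blood 0 sham arrays and 2 of the 4 arrays at 6 h were above background (adjusted p = 0.0421). The neutrophil granule gene Ltf reached 6.23 ± 1.40 in blood and was at least 18.2-fold higher in liver, against 0.93 ± 0.51 in spleen (adjusted p = 0.0393).

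The F test called 518 of 8120 genes at 6 h and 6 at 24 h, and 1736 and 687 had an unadjusted p under 0.05. On simulated data this test also called 39 unchanged genes beside 196 changed ones. At 24 h Clec9a was at least 11.1-fold lower in spleen, while in the other tissues sham means near background (5.90 to 6.33, against 9.08 in spleen) left little room for a fall, the tetraspanin gene Cd9 had values of 1.69 ± 0.24 in liver and -1.35 ± 0.48 in blood, and the phospholipase gene Pla1a of 2.72 ± 0.41 in lung and 2.59 ± 0.45 in spleen against -0.25 ± 0.22 in liver (adjusted p = 0.0372, 0.00405 and 0.0263). The replication and recombination genes Rfc4 and Mnd1 stood at 1.53 ± 0.29 and 1.48 ± 0.24 in spleen against -0.46 ± 0.23 and -0.46 ± 0.34 in liver (adjusted p = 0.0263 and 0.0381). The count at 6 h was 311 and 314 without liver sham replicates 1 and 2, 293 with the slide as a block and 759 without the raised sham arrays and liver 24 h replicate 3. At 24 h it was 0 without liver sham replicate 1, 24 without liver 24 h replicate 3, 19 without blood sham replicate 1, 15 without blood 24 h replicate 2, 1 to 3 without liver sham replicate 2, any lung sham array, any spleen sham or 24 h array, blood sham replicate 3 or blood 24 h replicate 1, and 154 without the raised sham arrays and liver 24 h replicate 3.

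Camera called 16, 20, 15 and 20 gene lists in liver, lung, spleen and blood at 6 h, of 42, 45, 45 and 43 tested, and 17, 32, 18 and 23 at 24 h. With an estimated correlation the cytokine list in blood at 6 h is the single call that holds. Fry, which tests whether the genes of a list move on balance one way, called 14, 15, 14 and 3 lists at 6 h and 0, 2, 6 and 0 at 24 h. The median, mean and camera direction differed in sign in 39 of 350 list results, and none of these is among the 161 that camera called.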

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

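All tests of explanations in this part were chosen after the results they concern had been seen. A sample counted as far from its group when its gap to the nearest sample, divided by the range of the 4, was above Dixon's critical value. Chance gives about 1 in 20 groups, and 23 of 323 tested groups were above it. A difference between tissues counted when the F test of the interaction passed, and unnamed probes counted as data outside the comparisons of genes.

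The sham arrays at 1 place of the slide layout carried raised acute phase genes such as Saa3 in all 4 tissues. In lung their median gene stood higher in the lone sham array (0.505 against 0.371), which carries liver RNA. On an axis from the other sham arrays (0) to the 6 h arrays (1), built from 200 genes, they scored 0.434 in liver, 0.393 in lung, 0.509 in spleen and 0.708 in blood. A swap of a sham and a PCI mouse needs a PCI place scoring under 0.1 in all tissues, and the largest number of tissues was 1, which argues against it. A 6 h array under a sham label is unlikely, since its interferon-stimulated genes reached at most 0.504 of their 6 h shift, and a 24 h array too, in liver and lung, since its clock index lay 0.967 above the highest 24 h array in lung, and 0.905 above it in liver with 24 h replicate 3, doubted below, left out. In spleen and blood this cannot be told apart, because the index lay among the 24 h arrays (-0.088 and -0.279 from the highest), which the lower of the other sham arrays exceeded by just 0.022 and 0.164. An effect of the whole slide is unlikely. Acute phase proteins exceeded those of its other sham array in all 4 tissues (median at least 0.628, lower quartile at least 0.178). In blood liver transcripts may add to this, and in lung that other array scored 0.443 from the lone sham array. No biological explanation was tested.

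Liver 24 h replicate 3 lay far below its group for Saa3 (gap 0.993; 7.40 against 15.86 in the nearest array) and Lcn2 (gap 0.984; 8.80 against 15.84). If 1 mouse is behind the arrays at each place, which the labels do not say, a mouse that did not respond is unlikely. Saa3 in the lung, spleen and blood arrays at the same place lay at least 4.632 log2 units above the other sham arrays. A swap with a liver sham array is unlikely too, since every liver sham array had a clock index at least 0.905 above the other 24 h liver arrays. A liver array of another mouse under this label could give its clock index, 1.77 above the highest other 24 h liver array, while the lung array at the same place lay within its group. Whether another error in handling gave the same result was not tested, nor was a biological explanation in which the liver alone did not respond.

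Liver transcripts in 4 blood arrays (6 h replicates 1 and 2, 24 h replicates 1 and 4) stood beside pancreas transcripts in 5 spleen arrays. The median hepatocyte gene had a log2 intensity of 10.39, 8.04, 7.46 and 7.66 in these blood arrays against 4.61 to 5.15 in the others. Acute phase genes switched on in blood cells would leave cytochrome P450 genes unmoved, but their median rose by at least 0.945 in each of the 4 arrays, which argues against this as the whole cause. Liver RNA mixed into the blood is a candidate source, since over 905 liver-enriched genes the rise went with the liver array at the same place with r of at least 0.731 (across genes, which are not independent replicates). Shared handling of the mouse at a place may be behind both, since the places coincide (Fisher's exact test, 2-sided, p = 0.0152 over 11 places). This rests on matching slides between tissues by the positions they hold, and with spleen slides 2 and 3 matched by number p was 0.242. A biological explanation, such as transcripts shed by injured organs, was not tested.

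Several arrays lay far from the other 3 of their group. Spleen 24 h replicate 4 lay high for Il6 (gap 0.94), Socs3 (0.974) and Stat3 (0.922) and low for Apol7c (0.881), Clec9a (0.866) and Cd27 (0.88). Lung 24 h replicate 1 lay high for Il6 (0.893), Il10 (0.888) and Stat3 (0.895), and liver 24 h replicate 1, at the same place, high for Il6 (0.854). Lung 24 h replicate 3 lay low for S100a9 (0.944), spleen 24 h replicate 3 low for Lcn2 (0.859) and blood 24 h replicate 2 low for S100a9 (0.894). At 6 h Tmem86a lay low in liver replicate 4 (0.885) and high in spleen replicate 3 (0.882), Lcn2 low (0.941) and Ifit2 high (0.94) in blood replicate 1. In lung at 6 h Cxcl2 lay low in replicate 2 (0.882), Mt2 high in replicate 4 (0.852), S100a8 low in replicate 3 (0.867) and Thbd low in replicate 1 (0.9).

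The tissue response differed at 6 h for G0s2 (adjusted p = 7.96e-06), Rsad2 (1.56e-05), Thbd (0.000257), Ccl19 (0.000525), Tmem252 (0.00212), Ackr1 (0.00346), Ptx3 (0.0153), Tlr2 (0.0212), Ltf (0.0393) and Adamts4 (0.0421). At 24 h it differed for Cd9 (0.00405), Pla1a (0.0263), Rfc4 (0.0263), Clec9a (0.0372) and Mnd1 (0.0381). Among probes without a gene name, 255 of 2788 passed in liver at 6 h, 283 of 3455 in lung, 472 of 3545 in spleen and 1 of 2601 in blood, and 109 of 3545 in spleen at 24 h.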

How the results depend on the processing

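The alternatives were chosen before the values were seen, apart from leaving out the arrays that stood apart, the common response of liver, lung and spleen alone, and those of the tests of slides, places and clock genes. Of 254 named gene results past the threshold, 138 lost their call without at least 1 array, 77 with the slide as a block, 61 with the replicate as a block, 51 without a filter, 30 with all arrays normalized together, 24 with the authors' values, 19 each without background correction and with 2 groups alone, 14 with an offset of 50, 3 each with cyclic loess and with the slide as a random block, and 1 with trend and robust eBayes. Array weights gave 45 further calls, and no named gene past the threshold turned in sign. Of 79 gene list results that camera called, 78 were lost with an estimated correlation, 40 with fry, 10 with the slide as a block and 8 without at least 1 array. Among the 79, the muscle list in lung at 24 h turned, to 0.233 with the slide as a block and 0.014 without lung sham replicate 1 (the lowest value, without sham replicate 2, was -1.535), as did the B cell list in blood at 24 h, to 0.004 with the slide as a block. Signals near the background leave dim genes untested, and the numbers of arrays limit the rest. Except where an alternative removes arrays, genes or calls by its own construction, the cause was not tested.

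With the slide as a block the common response at 6 h was 0 and the tissue difference 293. The counts were 766 in liver and 0 in blood at 6 h, and 0 in lung and 107 in spleen at 24 h. Between the times they were 2467, 4101, 3777 and 77 in liver, lung, spleen and blood. With the slide as a random block they were 1549 in lung and 2522 in spleen between the times. Array weights gave 5326, 2821 and 4310 in liver at 6 h, at 24 h and between the times, 4756, 190 and 4903 in lung, 5127, 3842 and 3842 in spleen, and 448 and 691 in blood at 6 h and between the times. With 2 groups alone the counts at 6 h were 2886 in liver, 4197 in lung and 139 in blood. At 24 h they were 0 in lung and 305 in spleen. Between the times they were 482, 309, 731 and 36 in liver, lung, spleen and blood.

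With an absolute log2 fold change of at least 1, 1205 genes passed in lung at 6 h, 337 in lung between the times, 1678 in spleen at 6 h, 367 at 24 h and 643 between the times. Counting all probes gave 1891 in liver at 6 h, 1387 in liver between the times, 4630 in spleen at 6 h, and 4 and 7 in blood at 6 h and between the times. Normalizing all 44 arrays together gave 0 in blood at 6 h, 2 in blood between the times and a common response of 0 at 6 h. Without a filter 1 gene passed in lung at 24 h, 8 in blood at 6 h, 2 in the common response at 6 h, and 1109 and 68 in the tissue difference at 6 h and 24 h. The stricter filter gave 142 in blood at 6 h, 60 between the times and 37 in the common response at 6 h. The authors' values gave 960 in spleen at 24 h, and 945 and 11 in the tissue difference at 6 h and 24 h. Without background correction 23 genes passed in blood between the times, and 783 and 13 in the tissue difference. Cyclic loess gave 47 in blood between the times. The share of higher calls between the times moved from 56.4% to 45.6% in spleen with cyclic loess, and in blood from 26.7% to 13.3% with an offset of 50 and to 50% of 2 calls with all arrays normalized together.

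Without liver sham replicate 3 and liver 24 h replicate 3, 558 genes passed in liver at 24 h. Without these and the other raised sham arrays the common response was 73 at 6 h and 1 at 24 h, and the tissue difference at 24 h was 154. Over liver, lung and spleen alone the common response at 6 h was 366.

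With the replicate number as a block, counts were 632 and 471 in liver at 6 h and between the times, 1146, 1 and 262 in lung at 6 h, at 24 h and between the times, 393 in spleen at 24 h, and 0 and 24 in blood at 6 h and between the times. Replicate numbers do not pair the arrays. After the group means were removed, arrays of the same number in 2 groups of a tissue had a median correlation of -0.028, and 10 of 40 pairs were above 0.1.

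Leaving out 1 array at a time gave 236 to 1353 in liver at 6 h, 0 to 123 at 24 h and 329 to 3096 between the times. In lung the counts ran from 442 to 1435, from 0 to 69 and from 149 to 4370, in spleen from 1313 to 2520, from 24 to 1219 and from 453 to 3714, and in blood from 0 to 162, from 0 to 1 and from 1 to 333. The common response ran from 0 to 69 at 6 h and the tissue difference from 311 to 697 at 6 h and 0 to 24 at 24 h. Correlations between tissues at 6 h ran from 0.434 to 0.513 for liver and blood, 0.672 to 0.690 for liver and lung, 0.562 to 0.594 for liver and spleen, 0.507 to 0.619 for lung and blood, 0.644 to 0.686 for lung and spleen and 0.518 to 0.583 for spleen and blood. At 24 h, in the same order, they ran from 0.073 to 0.261, 0.293 to 0.508, 0.152 to 0.353, 0.233 to 0.484, 0.289 to 0.436 and 0.299 to 0.428. Over genes past the threshold in 1 tissue of a pair or both, r at 6 h was 0.709, 0.75, 0.659, 0.756, 0.739 and 0.729 in that order, and at 24 h 0.550 for liver and spleen, 0.626 for lung and spleen and 0.692 for spleen and blood.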

Other observations

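The tests of places and of splits in this part were written down after the results had been seen. In liver at 6 h, 5 of 19 glucocorticoid-responsive genes, which stress hormones induce, rose and 1 fell (10 and 1 adjusted over the list alone) and in lung 7 of 18 rose (11 adjusted over the list alone). In liver their median was 1.18, or 1.01 with the slide as a block and 1.05 within slide 5 (camera adjusted p = 0.000227, adjusted p = 0.214 with an estimated correlation). In lung it was 1.27, or 1.15 with the slide as a block and 0.97 within slide 5 (camera adjusted p = 5.17e-05, adjusted p = 0.426 with an estimated correlation). In lung Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 3.07 ± 0.68 (adjusted p = 0.0986 with the slide as a block) and the metallothionein gene Mt2 by 4.41 ± 1.04. Immediate early genes, first to answer a stimulus, rose in 8 of 20 cases in liver (15 adjusted over the list alone), such as Ier3 (4.84 ± 1.26) and Atf3 (3.68 ± 0.72). Their median was 1.90, or 2.17 with the slide as a block and 2.04 within slide 5 (camera adjusted p = 6.68e-09, adjusted p = 0.298 with an estimated correlation). Oxidative stress genes rose in 9 of 23 cases in lung (10 adjusted over the list alone), with the cystine transporter Slc7a11 at 4.98 ± 1.14. Their median was 0.45, or 0.47 with the slide as a block and 0.23 within slide 5 (camera adjusted p = 0.0173, adjusted p = 0.36 with an estimated correlation). In spleen at 24 h glycolysis and hypoxia-responsive genes rose in 6 of 27 cases (7 adjusted over the list alone), the glycolytic enzyme Pgk1 by 1.12 ± 0.23 (adjusted p = 0.0622 with the slide as a block). Their median was 0.24, or 0.29 with the slide as a block and 0.22 within slide 5 (camera adjusted p = 0.0208, adjusted p = 0.51 with an estimated correlation).

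Arrays at the same place of the slide layout moved together across tissues once group means were removed, with a mean correlation across genes of 0.204 over 66 pairs and 8120 genes. Shuffling places within groups 10000 times gave at most 0.166 (one-sided permutation p = 1e-04, the lowest possible). With spleen slides 2 and 3 matched by number, not position, the mean was 0.137 (permutation p = 0.0012). One mouse behind each place is a candidate explanation. The 24 h arrays at 1 place (liver and lung replicate 1, spleen and blood replicate 4) scored 0.869, 0.960, 0.986 and 1.03 on the axis to 6 h, the highest at 24 h in each tissue. In spleen and blood this may reflect pancreas or liver transcripts, whose arrays scored highest in their groups.

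Every split of the 7 or 8 arrays of a comparison into groups of the real sizes was counted, 35 in each case. At 6 h only the real split gave as many genes (real, highest other) in liver (1251, 0) and lung (2044, 0). The same held in spleen (2988, 1) and blood (41, 2). It also held in spleen at 24 h (639, 242) and liver between the times (844, 475), but 35 splits cannot exclude chance. Between the times other splits gave as many (splits, real, highest) in lung (3, 582, 1757), spleen (2, 1284, 1298) and blood (3, 15, 157). They also did in lung at 24 h (5, 2, 13). With 0 genes in liver and blood at 24 h all 35 splits gave as many, the highest 979 and 687. The split with 979 sets liver sham replicates 1 and 2 and 24 h replicate 3 against the others, and that with 687 sets blood sham replicates 2 and 3 and 24 h replicate 2 against the others, so that both point to a structure of the samples other than their groups. The splits with 1757 and 1298 set the 24 h array of the place named above beside 6 h arrays, and point to the same, as does that with 157, which sets the 4 blood arrays with liver transcripts against the others. Of 100 splits drawn for the comparisons over all tissues, the real one included, 1 gave as large a common response at 6 h (16, highest other 0) and 3 as large a tissue difference at 6 h (518, highest other 767). For the common response this adds nothing to the counts of single tissues, since no other split of liver or lung at 6 h called any gene. For the tissue difference few splits gave as many, but the highest exceeded the real count. Each tissue was also split separately, which does not keep the places that tissues share, so chance is not excluded. At 24 h chance cannot be excluded either, with 100 splits for the common response (0, 0) and 17 for the tissue difference (6, 526).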
